A study of Homo sapiens with 20 samples.

How the data were processed

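RNA sequencing was done on whole blood from 10 psoriasis and 10 control individuals, and the labels' disease state put each of the 20 libraries in its group. The labels give no replicate numbers, so libraries were numbered within each group in deposit order, and the numbers pair nothing. Per the labels' protocols, RNA was extracted from PAXgene tubes, 200 ng entered a TruSeq library with 12 amplification cycles, and single reads of 50 bases were sequenced on 2 lanes of a HiSeq 4000. Per the submitters' processing notes, HTSeq 0.60 and the genome build GRCh37 (hg19) were used. The aligner, the annotation release, the strand setting and the tool that made the FPKM values are not given in the sources used here. How reads of overlapping genes, antisense genes and near-identical copies were counted is therefore not known.

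The authors deposited FPKM values (fragments per kilobase of gene, scaled for depth) for 58434 genes, rounded to 2 decimals. Their column totals differ while their upper quartiles nearly coincide, so the deposited FPKM scale each library by a size factor and not by its own total. The authors also deposited a table of psoriasis against control. Its first value is a signal level, the mean over the 20 libraries of counts divided by size factors, as the values of the deposited table show. It further holds log2 fold changes with and without shrinkage and their standard errors, a test score (the shrunken fold over its error), and p-values before and after adjustment, all made by the authors. The column names of the authors' deposited table are those that DESeq2 writes, and its version and settings are not given in the sources used here. Where values of that table are printed, they are the authors' own.

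Depth was estimated from both deposited tables together. For 3701 genes seen in a single library, the authors' mean level is a whole multiple of the step that 1 read adds, which gave each library's size factor, and with it the reads behind each FPKM value. Of 34484 values tested, 98.6% came out whole within 0.1 reads. Estimated reads in genes were 16.0 to 49.2 M per library. Values of low genes rest on few reads, and rounding to 2 decimals adds error below about the filter.

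Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with an intensity trend, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. Genes needed at least 0.5 FPKM in at least 10 of the 20 libraries, which left 12765 and set aside 45669. Fold changes are on the log2(FPKM + 0.5) scale and understate changes of low genes. No covariate was used. P-values measure the spread between individuals within each group. The 29 gene lists, the tests, the named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members, 26 in all, were tested with camera at a preset correlation of 0.01, and also with an estimated correlation, with fry, and by a permutation test (100000 resamples, smallest p 1e-05) of the mean log2 level per library. Adjusted p-values of lists are over the 26 lists. Where a member count is called adjusted over the list alone, the limma p was adjusted within that list.

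Named genes were chosen by rule. They are the 10 genes per direction past the threshold with the largest folds and a mean of at least 1 FPKM, filled where fewer passed with the smallest p and then said not to pass. To these were added inflammasome members with an unadjusted p under 0.05 and always CASP1, CASP5, IL1B, NLRP3, AIM2 and PYCARD. From each other list came up to 4 members with the smallest p in the list's direction where the list passed and up to 2 where it did not. A gene that this rule names is not reported here. Genes of the sex chromosomes used to tell samples apart, immunoglobulin and T cell receptor segments and names without a gene symbol were left out. Genes of the authors' table outside this rule, and those named in the closing section, were chosen after their values were seen. The files give no coordinates, and the annotation at hand (GENCODE 29) is of another build, so none are printed. It was used only for chromosome names of genes.

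The limma fit was checked on simulated log2 data made from the means and spreads of the 12765 genes, with 10 libraries per group and 200 changed genes in each of 5 simulations. Of the genes changed 1.3-fold 41.2% were called, of those changed 1.5-fold 74.0%, of those changed 2-fold 90.4% and of those changed 3-fold 98.0%. Unchanged genes made up 3.90% of calls, and the dendritic cell list, shifted by -0.30, was called in 5 of 5 simulations. The shares called hold for 200 changed genes and would be lower with fewer, because the adjusted threshold then tightens. They therefore do not measure what the fit of the real data could miss. Simulated genes varied independently, which real blood does not.

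Alternatives changed 1 choice at a time: the pseudocount, the filter, 3 rescalings, the trend, library weights, marker covariates, the thresholds, the list test, and each library left out in turn. Added after seeing the data were voom on the estimated reads (with the same genes, and with at least 5 reads on average), fits without 3 sets of libraries, and the dendritic cell and monocyte list differences as results of their own. A count test was not run, because the deposited unit is FPKM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots. No pair of libraries was identical.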

Results

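Whole blood, the mixture of red cells, platelets and white cells, was collected in tubes that stabilise RNA from individuals with psoriasis, a chronic inflammatory disease of the skin, and from controls. RNA sequencing gave 20 libraries, 10 from psoriasis and 10 from control. The comparison asks how the blood transcriptome differs between the groups, with the inflammasome, the protein assembly that activates caspase-1 and the cytokines interleukin-1 beta and interleukin-18, as the pathway of interest. Estimated reads in genes ranged from 16.0 to 49.2 M reads per library with a median of 20.5 M, and Psoriasis replicate 10 held the highest number. The group means were 23.6 M ± 9.05 (SD, n = 10) in psoriasis and 20.2 M ± 2.31 (SD, n = 10) in control. Globin transcripts of red cells took 31.8% ± 11.1 (SD, n = 10) of reads in psoriasis and 35.0% ± 9.35 (SD, n = 10) in control, with single libraries between 13.6% and 51.7%. Neither depth (permutation p = 0.285, two-sided) nor globin share (permutation p = 0.483, two-sided) differed beyond the spread between libraries. A check for mixed samples marked 4 of the 20 libraries, 2 in each group.

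CASP5, the caspase that senses bacterial lipopolysaccharide inside cells, and SOCS3, an inhibitor of cytokine signalling, had the largest fold changes among the 10 higher genes with the smallest p in psoriasis blood, and FUCA1, a lysosomal fucosidase, had the smallest p of all genes. CASP5 stood at 6.83 FPKM ± 3.4 (SD, n = 10) in psoriasis and 2.57 FPKM ± 0.512 (SD, n = 10) in control. SOCS3 stood at 33.1 FPKM ± 32.0 and 9.74 FPKM ± 2.75, and FUCA1 at 8.80 FPKM ± 1.05 and 12.5 FPKM ± 1.85 (SD, n = 10 each). None of these differences passed the test over all genes. Of 12765 genes tested with limma, 0 were higher and 0 were lower at an adjusted p of 0.05, and the lowest adjusted p was 0.195, for FUCA1. At an unadjusted p under 0.05 there were 694 genes, 315 higher and 379 lower in psoriasis, where 638 are expected by chance. The same tool gave 11 higher and 22 lower genes with array quality weights, 6 and 4 with the mature neutrophil marker mean as a covariate, and 172 and 11 with the T cell marker mean as a covariate. A limma voom fit on estimated reads gave 0 and 0, and limma without the 4 libraries marked by the mixed-sample check gave 0 and 0 with 375 genes at an unadjusted p under 0.05.

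The genes with the smallest p in each direction are given as values, since none passed. On the side of higher expression in psoriasis, the log2 fold change was 1.11 ± 0.25 (SE, n = 10 per group) for CASP5 and 1.37 ± 0.32 for SOCS3. It was 0.99 ± 0.27 for FCGR1A and 0.95 ± 0.25 for FCGR1B, near-identical copies of the high-affinity receptor for immunoglobulin G whose reads can be confused. C1QB, a chain of the first complement component, gave 1.06 ± 0.29, and CMTM8 0.51 ± 0.13. FAM222B (0.24 ± 0.06), LGALS8 (0.26 ± 0.06), DMWD (0.27 ± 0.07) and SLC39A8, a zinc transporter (0.23 ± 0.06), had small folds with narrow spread. FAM222B was above every control library in 10 of 10 psoriasis libraries. CASP5 was above every control in 9 of 10, while Psoriasis replicate 7, at 1.29 FPKM, lay below every control. Without that library limma called CASP5 higher (log2 fold change 1.31, adjusted p = 0.00178) and RPGRIP1 lower (-0.77, adjusted p = 0.0106). That library was also the highest psoriasis library for RPGRIP1, at 3.03 FPKM. It ran against the direction of both genes, so leaving it out favours these calls and they are not support. No other single library left out gave a call.

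On the side of lower expression, FUCA1 gave a log2 fold change of -0.48 ± 0.09 (SE, n = 10 per group) and RPGRIP1 -0.68 ± 0.14. CD1D, which presents lipids to natural killer T cells, gave -0.38 ± 0.08. CLEC10A, a lectin of conventional dendritic cells, gave -0.64 ± 0.16, and CSF1R, the receptor for the monocyte growth factor CSF1, gave -0.39 ± 0.10. The others were CDK5R1 (-0.76 ± 0.17), DTX4 (-0.71 ± 0.17), NOV (-0.84 ± 0.21), GPX3, an extracellular glutathione peroxidase (-0.71 ± 0.17), and GPD2 (-0.34 ± 0.08). All 10 psoriasis libraries lay below the control median for FUCA1, CD1D, CDK5R1, DTX4, GPD2, CLEC10A and CSF1R.

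Within the inflammasome list, CASP5, IL1B and NAIP were at higher and IL18 at lower levels in psoriasis at an unadjusted p under 0.05, while the means of CASP1, NLRP3 and PYCARD stayed near those of control. IL1B, the precursor of interleukin-1 beta, stood at 21.9 FPKM ± 7.52 (SD, n = 10) in psoriasis and 15.2 FPKM ± 4.51 (SD, n = 10) in control, a log2 fold change of 0.51 ± 0.18 (SE). NAIP, a sensor of bacterial proteins, gave 0.45 ± 0.16, and AIM2, a sensor of DNA in the cytosol, 0.38 ± 0.26. IL18 gave -0.42 ± 0.11, with all 10 psoriasis libraries below the control median. The log2 fold change was 0.08 ± 0.15 for CASP1, 0.01 ± 0.17 for NLRP3 and -0.0010 ± 0.18 for the adaptor PYCARD, and the sign of each of these 3 turned in at least 1 other setting. Single psoriasis libraries spread more widely for 2 of them. PYCARD lay below every control in 4 and above every control in 2. CASP1 lay below every control in 1 and above every control in 4. Of the 25 members tested, 15 had a higher and 10 a lower mean in psoriasis. CASP5 and IL18, 2 genes, passed when adjusted over the list alone, and 0 passed when adjusted over all genes. The list did not pass as a set (camera adjusted p = 0.394, and adjusted p = 0.941 with an estimated correlation). The mean log2 level over the list was 3.59 ± 0.24 (SD, n = 10) in psoriasis and 3.49 ± 0.16 (SD, n = 10) in control. The difference of 0.10 ± 0.09 (SE) lay within the spread between libraries (permutation p = 0.292, two-sided). With the T cell marker mean as a covariate the difference was 0.19 (permutation p = 0.00299), and without Psoriasis replicates 4 and 8 it was 0.01 (permutation p = 0.889).

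**Figure D1:**
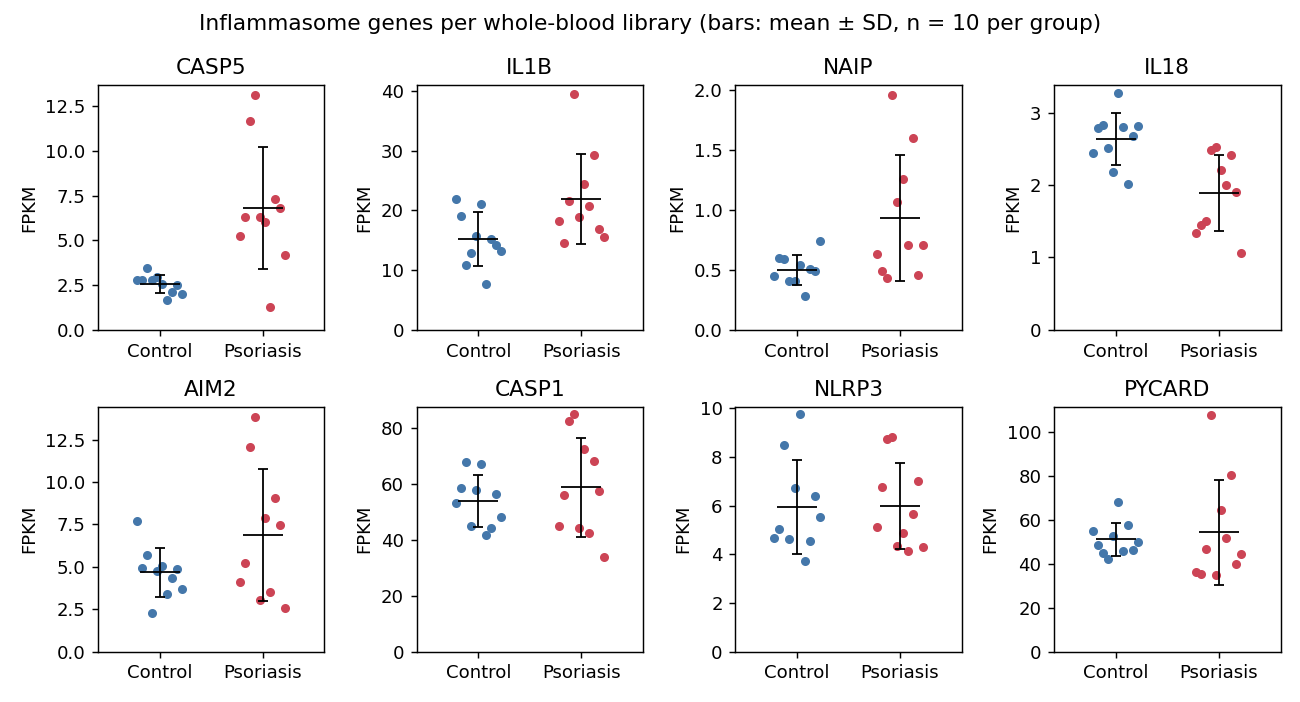
FPKM of 8 inflammasome genes in each whole-blood library (points), with the mean and SD of the 10 control and 10 psoriasis libraries as bars, each panel on its own axis from 0. CASP5 lies above every control in 9 psoriasis libraries and below every control in 1, IL18 lies below the control median in all 10, and CASP1, NLRP3 and PYCARD overlap.

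Markers of dendritic cells, the antigen-presenting cells that make up a small part of blood leukocytes, fell in psoriasis. Of 11 members tested, 10 had a lower mean and 1 a higher mean, with a median log2 fold change of -0.38. CLEC9A, a receptor of cross-presenting dendritic cells, gave -0.75 ± 0.23 (SE, n = 10 per group), CLEC10A -0.64 ± 0.16, the growth factor receptor FLT3 -0.47 ± 0.16 and CD1D -0.38 ± 0.08. These 4 passed when adjusted over the list alone and 0 passed over all genes. CLEC9A (0.72 FPKM ± 0.41 in psoriasis, 1.63 FPKM ± 0.95 in control) and FLT3 (0.64 FPKM ± 0.23 and 1.11 FPKM ± 0.53, SD, n = 10 each) lay near the filter. The plasmacytoid markers CLEC4C (-0.38 ± 0.31) and LILRA4 (-0.24 ± 0.17) and the conventional marker CD1C (-0.14 ± 0.16) had wide intervals, and IRF8 (-0.02 ± 0.10) and PLD4 (0.01 ± 0.14) were level. The list passed with limma camera (adjusted p = 6.3e-07) and was the only list past the threshold with an estimated correlation (adjusted p = 0.000556 with an estimated correlation). The mean log2 level over the list was 1.94 ± 0.13 (SD, n = 10) in psoriasis and 2.28 ± 0.12 (SD, n = 10) in control, a difference of -0.34 ± 0.06 (SE), and 9 of 10 psoriasis libraries lay below every control. The permutation test of this difference gave p = 2.0e-05, two-sided, and p = 0.00052 after adjustment over the 26 lists. GZMB (-0.46 ± 0.28) is also a cytotoxic cell gene, IRF8 is also in the interferon gamma list, and CD1D is also made by monocytes. Without these 3 the difference was -0.36 (permutation p = 7.0e-05).

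**Figure D2:**
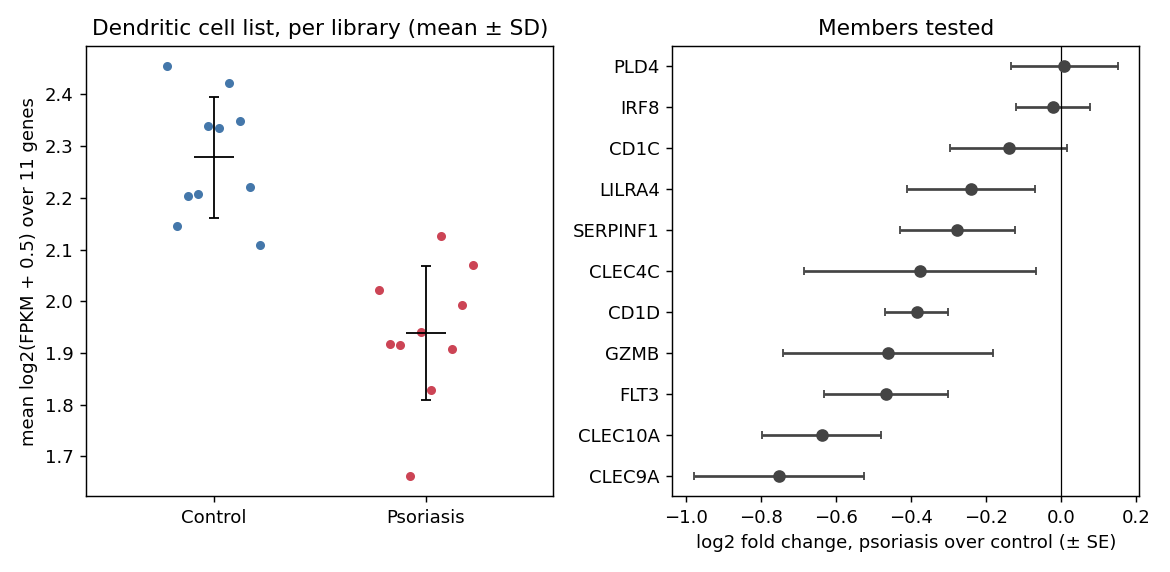
Left, mean log2(FPKM + 0.5) over the 11 tested dendritic cell markers in each library, with the mean and SD of each group of 10. Right, log2 fold change of each member, psoriasis over control, with its SE; 10 of the 11 lie below 0.

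A further 6 of the 26 lists tested passed with the preset correlation of 0.01 but none of these 6 passed with an estimated correlation. Interferon-stimulated genes were shifted upward: 32 of 32 type I interferon genes had a higher mean in psoriasis, with a median log2 fold change of 0.34 (adjusted p = 0.000752, and adjusted p = 0.941 with an estimated correlation). The antiviral membrane protein IFITM3 gave 1.17 ± 0.47 (SE), IFITM1 0.59 ± 0.27, OASL 0.62 ± 0.47 and IFI27 1.12 ± 0.97. This call was lost without Psoriasis replicate 3 (adjusted p = 0.404) and without Control replicate 7. B cell markers were shifted upward with 20 of 20 members at a higher mean and a median of 0.32 (adjusted p = 2.6e-05, and adjusted p = 0.941 with an estimated correlation). Among them were FCRLA (0.44 ± 0.24), CR2 (0.36 ± 0.20) and RALGPS2 (0.20 ± 0.12). The B cell call was kept without any single library but lost without the pair of libraries with another tube name, 1 per group (adjusted p = 0.136), and with the T cell marker mean as a covariate (adjusted p = 0.0529). T cell markers had 19 of 21 members at a higher mean (median 0.11, adjusted p = 0.00171, and adjusted p = 0.941 with an estimated correlation), with CD28 at 0.24 ± 0.14, CD6 at 0.22 ± 0.13, CD27 at 0.18 ± 0.11 and CD5 at 0.21 ± 0.13.

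Toll-like receptor genes, which sense microbial products, had 16 of 18 members at a higher mean in psoriasis (median 0.10, adjusted p = 0.00202, and adjusted p = 0.915 with an estimated correlation). TLR5, the flagellin receptor, gave 0.65 ± 0.22 (SE), the adaptor MYD88 0.35 ± 0.14, TLR10 0.34 ± 0.15 and CD14 0.38 ± 0.19. Platelet markers had 21 of 23 members at a higher mean (median 0.17, adjusted p = 0.0119, and adjusted p = 0.941 with an estimated correlation), with SELP at 0.36 ± 0.17, MYL9 at 0.69 ± 0.45, CMTM5 at 0.34 ± 0.27 and PTGS1 at 0.18 ± 0.17. Without Psoriasis replicates 4 and 8 the platelet list turned downward (adjusted p = 0.622), so its upward direction rests on that pair. Cytotoxic T and natural killer cell markers went the other way, with 20 of 25 members at a lower mean (median -0.18, adjusted p = 0.0119, and adjusted p = 0.941 with an estimated correlation). KLRC1 gave -0.63 ± 0.22, SH2D1B -0.55 ± 0.26, NCAM1 -0.24 ± 0.13 and GZMB -0.46 ± 0.28. In these 6 lists 0 members passed when adjusted over the list alone. The platelet list passed in 15 of 20 fits that left out a single library, failing without Psoriasis replicate 1, 4 or 8 or Control replicate 4 or 7 (adjusted p up to 0.633), and the cytotoxic list in 14, failing without Psoriasis replicate 3, 4, 6 or 8 or Control replicate 7 or 8 (adjusted p up to 0.304). Without Control replicate 7 only 3 lists passed, those of B cells, T cells and dendritic cells, and the Toll-like receptor call was also lost without Psoriasis replicates 4 and 8 (adjusted p = 0.124). Of the 17 other settings, the interferon list passed in 17, the T cell and Toll-like receptor lists in 16 each, the B cell list in 15, the cytotoxic list in 14 and the platelet list in 13. All of these settings, and the fits without a single library, kept the preset correlation of 0.01. The permutation test of the library means gave p = 0.441 for the interferon, 0.232 for the B cell and 0.257 for the T cell list. It gave p = 0.119 for the Toll-like receptor, 0.478 for the platelet and 0.412 for the cytotoxic list.

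**Figure D3:**
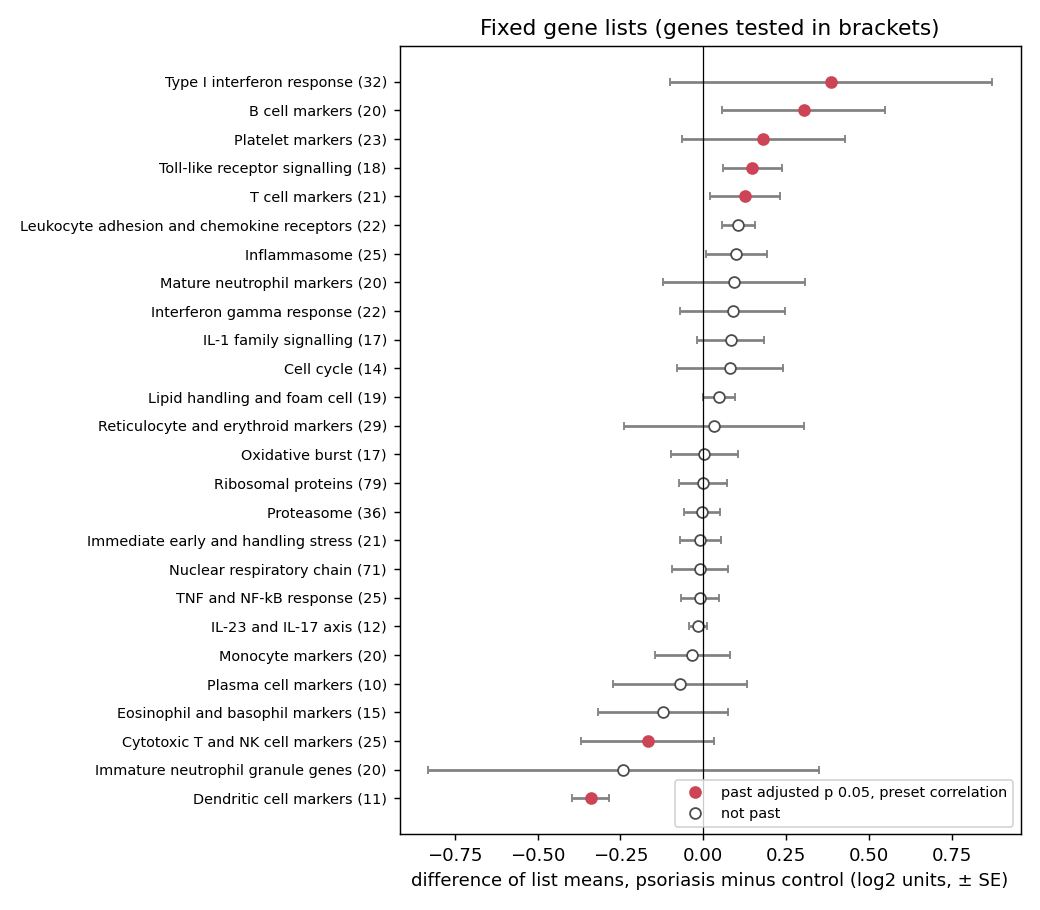
Difference of the mean log2 level between psoriasis and control for the 26 gene lists tested, with its SE and the number of genes tested in brackets. Filled points mark the 7 lists past an adjusted p of 0.05 with the preset correlation; the dendritic cell list lies lowest, at -0.34, and the type I interferon list highest, at 0.39 with a wide SE of 0.49.

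The remaining 19 lists did not pass, the inflammasome list included. Beside that list, members that passed when adjusted over the list alone numbered 4 in the TNF and NF-kB list, 2 in the interferon gamma list, 1 in the IL-1 family list and 1 among monocyte markers, with 0 in the others and 0 over all genes. Among inflammatory pathways, the IL-1 family list gave an adjusted p of 0.362, the TNF and NF-kB list 0.695, the interferon gamma list 0.362 and the IL-23 and IL-17 list, the axis most tied to psoriatic skin, 0.695. CXCL8, the neutrophil attractant, was at 2.75 FPKM ± 1.11 (SD, n = 10) in psoriasis and 5.90 FPKM ± 2.94 (SD, n = 10) in control, a log2 fold change of -0.93 ± 0.27 (SE), with all 10 psoriasis libraries below the control median. IER3 gave -0.46 ± 0.14, TYK2 -0.18 ± 0.09 and IL23A 0.20 ± 0.12. The leukocyte adhesion and chemokine receptor list gave an adjusted p of 0.0530, with CCR1 at 0.71 ± 0.23 and CX3CR1 at 0.27 ± 0.14. The lipid handling list (adjusted p = 0.695) held ACSL1 at 0.47 ± 0.23 and ABCA1 at 0.35 ± 0.20, and the oxidative burst list (adjusted p = 0.715) held PADI4 at -0.45 ± 0.25 and NCF1 at -0.19 ± 0.12.

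Among blood cell markers, mature neutrophil genes gave an adjusted p of 0.441, with PROK2 at 0.91 ± 0.30 (SE) and ALPL at 0.88 ± 0.34. Immature neutrophil granule genes gave 0.176, with DEFA3 at -1.35 ± 0.76 and MS4A3 at -0.54 ± 0.35. Monocyte markers gave 0.240, with CSF1R at -0.39 ± 0.10 and the lysosomal protease CTSS at -0.32 ± 0.10, both below the control median in all 10 psoriasis libraries. The monocyte list passed, shifted downward, without Psoriasis replicate 4 (adjusted p = 0.0214, and adjusted p = 0.963 with an estimated correlation) and without Psoriasis replicates 4 and 8 (adjusted p = 0.00306, and adjusted p = 0.882 with an estimated correlation). The adjusted p was 0.695 for plasma cells (XBP1 -0.16 ± 0.08, JCHAIN -0.55 ± 0.44), 0.176 for eosinophils and basophils (CCR3 -0.63 ± 0.23, CPA3 -0.34 ± 0.21) and 0.860 for erythroid genes (KRT1 0.68 ± 0.35, FAM46C -0.23 ± 0.18).

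Among general groups, the cell cycle list gave an adjusted p of 0.240 (MCM2 0.16 ± 0.12, CCNA2 0.20 ± 0.15, SE) and the immediate early list, which responds to blood handling, 0.394 (JUNB 0.43 ± 0.17, and CXCL8, also in this list, -0.93 ± 0.27). Ribosomal proteins gave 0.664 (RPL39L 0.44 ± 0.20, RPL9 0.86 ± 0.46), the nuclear respiratory chain 0.715 (UQCRC2 -0.11 ± 0.06, NDUFS8 0.15 ± 0.09) and the proteasome 0.999 (PSMD3 0.10 ± 0.06, PSMB5 0.15 ± 0.09). PSMD3 turned to -0.035 once globin genes were removed and the others rescaled, and this rescaling shifted the median of all genes by -0.13. The skin and endothelial lists had 2 and 4 members above the filter, fewer than the 5 needed, and were not tested. The mitochondrially encoded list had 0 members among the deposited genes, so it could not be tested. Of the 19 lists that did not pass, 9 passed in at least 1 of the 20 fits that left out a single library, and 0 of these calls held with an estimated correlation. They were the adhesion list in 9 fits, immature neutrophils in 5, the cell cycle in 3, the interferon gamma, eosinophil and ribosomal lists in 2 each, and the monocyte, erythroid and respiratory chain lists in 1 each.

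The authors' deposited table of psoriasis against control lists 30 genes at an adjusted p under 0.05, 10 higher and 20 lower in psoriasis. By that table SYCP2L had the smallest adjusted p (2.3e-05) with an unshrunken log2 fold change of -2.68. The authors' deposited table gives CASP5 at 1.41 (adjusted p = 0.000234) and KRT72, a hair follicle keratin, at -1.51 (adjusted p = 0.000234). It also lists SOCS3 at 1.25 (adjusted p = 0.00161) and the complement chains C1QA at 1.18 and C1QB at 1.77 in the authors' deposited table. Of the 30 genes, 21 passed the filter on FPKM used with limma, and 9 lay below it, among them SYCP2L, ANGPT1 and SIGLEC12. SYCP2L stood at 0.0510 FPKM ± 0.0592 (SD, n = 10) in psoriasis and 0.325 FPKM ± 0.141 (SD, n = 10) in control, with 9 of 10 psoriasis libraries below every control. All 30 had the same direction in limma, and the 21 had an unadjusted p under 0.05 with limma adjusted p from 0.195 to 0.870. Adjusted over the list alone 29 passed with limma, which is not independent evidence because the list was chosen on these samples. Over the 12765 genes tested, the log2 fold changes of limma and of the authors' deposited table correlated across genes with r = 0.924, and genes are not independent replicates.

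For most genes the unshrunken fold in the authors' deposited table equalled the ratio of the mean FPKM, within 0.05 on the log2 scale for 98.1% of 12765 genes. A gap over 0.3 occurred in 49 genes. These included 2 of the 21 genes past the threshold of the authors' deposited table. KRT72 had a ratio of -0.25 on the log2 scale against -1.51 in the authors' deposited table, and SOCS3 a ratio of 1.76 against 1.25. KRT72 stood at 21.3 FPKM in Psoriasis replicate 10, above every control, while 9 of 10 psoriasis libraries were below the control median.

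**Figure D4:**
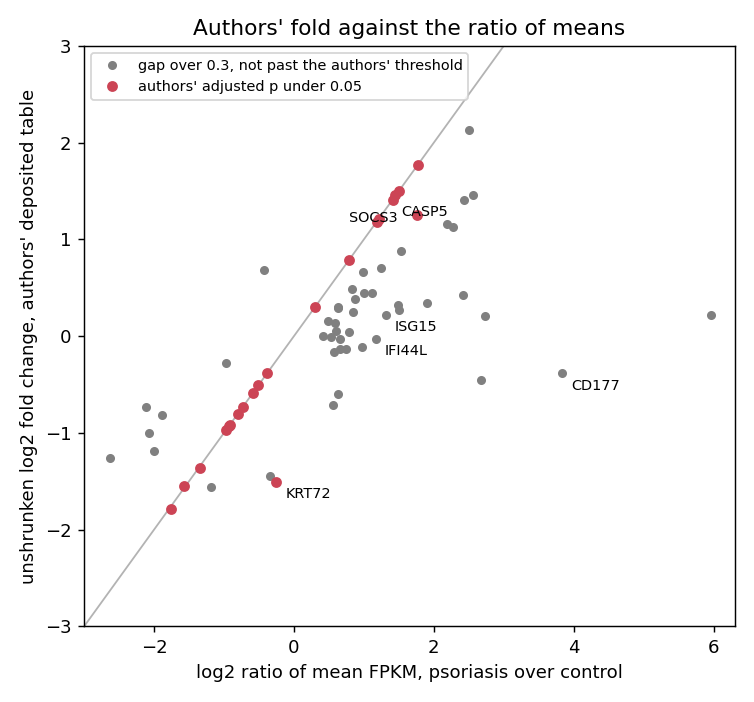
Unshrunken log2 fold change in the authors' deposited table against the log2 ratio of mean FPKM, psoriasis over control, for the 21 tested genes past the authors' threshold (red) and the genes with a gap over 0.3 (grey); the line marks equal values. CASP5 lies on the line, and KRT72 and SOCS3 lie off it.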

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

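Each group of 10 libraries was searched for a library far from the other 9, by the gap to its neighbour over the whole range, for every named gene, every list mean, depth and globin share. Of 222 such groups 10 held a library this far out, where about 11 are expected by chance, so the number shows no excess.

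CASP5 stood at 1.29 FPKM in Psoriasis replicate 7, against 4.2 to 13.1 in the other psoriasis libraries, and the IL-23 and IL-17 list mean of the same library was the highest of its group at 2.64, against 2.39 to 2.51. CXCL8 stood at 0.610 FPKM in Psoriasis replicate 4, against 1.81 to 4.6. In Psoriasis replicate 10, the most deeply sequenced library with 49.2 M estimated reads against 19.7 to 23.0 M in its group, CTSS was lowest at 191 FPKM (others 251 to 304) and UQCRC2 lowest at 11.3 FPKM (others 13.8 to 16.7). Control replicate 4 was lowest for the platelet gene MYL9 at 0.540 FPKM (others 3.52 to 9.51) and for the platelet list mean at 1.83 (others 2.67 to 3.48). Control replicate 7 was lowest for the TNF and NF-kB list mean at 3.4 (others 3.61 to 3.83) and for the leukocyte adhesion and chemokine receptor list mean at 5.23 (others 5.37 to 5.46).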

How the results depend on the processing

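Fits on voom and fits without sets of libraries were chosen after the data were seen, and so was the dendritic cell list difference. The count of 0 higher and 0 lower genes moved to 11 and 22 with array quality weights, 6 and 4 with the mature neutrophil covariate, and 172 and 11 with the T cell covariate. Voom on at least 5 reads called 0 higher and 1 lower gene, SYCP2L. The 7 lists became 12 with the T cell covariate, 1 with an estimated correlation and 1 with fry, both the dendritic cell list. The platelet list turned downward without the pair of libraries highest on component 1, and the T cell list with its own mean as the covariate, neither past the threshold. The authors' deposited table goes from 30 to 64 genes at an adjusted p of 0.10. The inflammasome difference of 0.10 was 0.19 with the T cell covariate. It turned to -0.028 once globin genes were removed and the others rescaled, a step that shifted the median of all genes by -0.13. Leaving out single libraries gave 0 to 1 higher genes, 0 to 1 lower genes, 3 to 10 lists, an inflammasome difference of 0.05 to 0.14 and a dendritic cell difference of -0.36 to -0.31, and the single calls came without Psoriasis replicate 7. NLRP3 turned to -0.13 without globin, -0.018 with the neutrophil covariate and -0.054 without the pair of libraries highest on component 1. CASP1 turned to -0.066 and -0.028 without globin and without that pair, and PSMD3 to -0.035 without globin. PYCARD turned to 0.0014 with median-of-ratios scaling, 0.16 with the T cell covariate, 0.0019 and 0.00096 with voom, and 0.016 without a pair of libraries with another tube name. After globin removal, all genes of a library were multiplied by the same factor, its total FPKM over its FPKM without globin. The deposited FPKM are scaled by size factors, so removal without this rescaling would change no other gene. The turns of the inflammasome difference, NLRP3, CASP1 and PSMD3 in that setting therefore go with the rescaling, which shifted all genes by -0.13. The cause of the other changes was not tested, except for the T cell covariate. The dendritic cell list passed in the 17 other settings and in 20 of 20 fits without a library. The count test was not run. Depth limits genes with few reads, such as SYCP2L. No paired analysis was made, because the groups are different individuals and the labels give no pairing between them.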

Other observations

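Tests chosen only after the result was seen are the fits without sets of libraries, the further fits around the T cell covariate, the dendritic cell tests on globin share, depth and the monocyte list mean difference, with and without some libraries, and without some members, and the naming of genes in this part. The largest axis of variation between these blood libraries was not psoriasis. Component 1 held 21.3% of the variance and did not separate the groups (permutation p = 0.777). The genes at its high end included the neutrophil surface protein CD177, immunoglobulin segments, the interferon-stimulated gene IFI27 and the granule genes PRTN3, DEFA4, ELANE, LTF and LCN2. Its low end was made up mostly of T cell receptor segments. Psoriasis replicates 4 and 8 were highest on it at 61.2 and 35.3. CD177 stood at 210 FPKM in Psoriasis replicate 4.

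With the mean of the T cell markers as a covariate, a setting fixed before the data were examined, 172 genes rose in psoriasis at equal T cell marker level, among them PROK2, ALPL and ANXA3 of the mature neutrophil list (adjusted p = 3.6e-06 for the list, and adjusted p = 0.106 with an estimated correlation). PROK2, a neutrophil chemokine-like protein, gave a log2 fold change of 1.26 ± 0.12 (SE) with adjusted p = 1.4e-05, PFKFB3, a driver of glycolysis, 0.86 ± 0.10, the glucose transporter SLC2A3 0.76 ± 0.10, SOCS3 1.69 ± 0.21, VNN1 1.43 ± 0.20, ACSL1 0.73 ± 0.11 and TLR5 0.89 ± 0.12. Of the inflammasome list, 3 members were called higher, CASP5, IL1B and NAIP. The IL-1 family (adjusted p = 0.0386 with an estimated correlation), Toll-like receptor (adjusted p = 0.0260 with an estimated correlation) and dendritic cell lists (adjusted p = 0.00104 with an estimated correlation) passed either way in this fit. Whether these list calls hold in this fit without Psoriasis replicates 4 and 8 was not tested. The inflammasome list passed with the preset correlation (adjusted p = 0.0145) and not with an estimated one (adjusted p = 0.370 with an estimated correlation). The T cell marker mean was itself 0.13 higher in psoriasis. Without the covariate the mature neutrophil list mean differed by 0.09 (permutation p = 0.674). Psoriasis replicates 4 and 8 had the highest mature neutrophil means, 7.83 and 7.47, with T cell means of 3.62 and 3.97, so they may weigh heavily on this adjustment.

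This fit called 183 genes, 172 higher and 11 lower, where the fit without a covariate called 0, and 90 of the 183 had an unadjusted p under 0.05 without it. Among 100 splits of the libraries with the same covariate, 1, the real one, gave as many, and the highest other gave 78. Within this setting a random grouping therefore seldom gives as many. This was, however, the setting with the most calls among those tried, and the splits do not account for that choice, so chance is not excluded. Adding the globin share as a second covariate left 227 calls. That share did not differ between the groups beyond its spread, so this is weak evidence about globin content. Without Psoriasis replicates 4 and 8 only 13 genes were called, 8 of them among the 183. Although 182 of the 183 kept their direction, 137 had a smaller fold, with the median log2 fold change in absolute value going from 0.53 to 0.40. Among the smaller folds were SOCS3 at 1.05, PFKFB3 at 0.51, TLR5 at 0.55, and ZDHHC19, from 1.28 to 0.039. Others grew, such as PROK2 from 1.26 to 1.37 and ACSL1 from 0.73 to 0.86. Leaving out single libraries gave 57 to 239 calls, the lowest without Psoriasis replicate 4, so the size of this set may rest largely on Psoriasis replicates 4 and 8, and whether they reflect disease or another state of the donors was not tested.

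Without a covariate, 27 of 100 splits gave at least 694 genes at an unadjusted p under 0.05, with 1892 the highest of the others, and 4 splits called some gene at an adjusted p of 0.05. At least 7 lists passed in 78 of the 100 splits, with 20 the highest of the others. Chance is therefore not excluded for either count.

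The dendritic cell list is the exception among the lists, with a difference of -0.34 that lay beyond its spread in each setting tried. With globin share and depth as covariates it was -0.34 ± 0.06 (SE). Neither covariate differed between the groups beyond its spread, so this fit could hardly have moved the difference and decides nothing about them. With the monocyte list mean as a covariate it was -0.35 ± 0.04, but that mean differed too little between the groups to bring the difference near 0 and its slope was negative (-0.36 ± 0.08), so this bound decides nothing about a shared monocyte shift. That and a lower share of all myeloid cells stay open: the monocyte list difference of -0.03 ± 0.11 became -0.11 ± 0.09 without Psoriasis replicate 4 and -0.17 ± 0.08 (permutation p = 0.0414) without both, the dendritic minus monocyte difference was -0.31 ± 0.16 (permutation p = 0.0606) and -0.14 ± 0.12 (permutation p = 0.241) without both, and CSF1R and CTSS lay below the control median in all 10 psoriasis libraries. The 7 members left after removing CD1D, CLEC10A, CLEC9A and FLT3 gave -0.21 (permutation p = 0.0286), and whether dendritic cells were fewer or held less of these transcripts per cell was not tested.

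In 49 genes the unshrunken fold of the authors' deposited table departs from the ratio of mean FPKM by over 0.3 on the log2 scale, a pattern first noticed in KRT72 and SOCS3. Replacing the most extreme library of each gene by the trimmed mean of all 20 (0.2 trimmed at each end) brought the median gap from 0.87 to 0.0018, and 41 of the 49 came within 0.05, while the same replacement moved the median gap of the other genes from 0.0020 to 0.07. A candidate explanation is that single extreme values were replaced before the authors' test. Rounding of FPKM is argued against by the level of these genes, with a median mean of 6.42 FPKM. The extreme library was Psoriasis replicate 4 in 27 of the 49 and Psoriasis replicate 3 in 8, among them ISG15 at 1084 FPKM, and no biological explanation was tested.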
